A study of Mus musculus with 36 samples.

How the data were processed

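Liver RNA was measured on whole-transcript Affymetrix gene arrays, 1 array per sample, in 36 samples. The samples fall into 12 groups of 3, given by 2 diets and 6 harvest times, and each sample took its group and number from the labels. The labels number 3 samples per group and speak of animals, without saying more about how they were kept apart, so p-values measure the spread between these samples.

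The values deposited hold 35556 probe sets with a linear intensity per array, and the authors used Affymetrix Expression Console 1.1.1 and PLIER 2.0 to make these values, per the submitters' processing notes. The background correction and the normalization between arrays are not given in the sources used here. The deposited intensities ran from near 0 to 19474, and array medians lay between 75.7 and 95.6. Arrays had similar but not identical distributions, with interquartile ranges from 1.94 to 2.32 on the log2 scale. No pair of arrays of 1 group held identical values. The fits used the values without further scaling, after log2(intensity + 16). A log2 difference on this scale understates the change of dim probe sets. Because the number of arrays limits the precision, group differences are given with the standard error of the fit.

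Probe sets were named through the platform annotation, with symbols updated by entrez identifier for 99.6% of the single-gene probe sets. The annotation paired 21789 probe sets with 1 gene and 1621 with several, and 12146 probe sets were not listed and are unnamed here. The single-gene probe sets covered 19938 genes, of which 999 had more than 1 probe set and were represented by the brightest over all samples. Genes above the 30th percentile of mean intensity, a log2 value of 6.11, were tested, which left 13956 genes. Of the 985 symbols in the gene lists, 805 were tested, and the others are not analysed here.

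Diet effects came from a limma fit with 1 mean per diet and time, so that all 36 arrays share an estimate of the spread with 24 residual degrees of freedom. The average effect is the mean of the 6 high fat diet groups minus the mean of the 6 chow groups. The same fit gave the contrast at each time. Rhythm was tested in a second limma fit with a diet mean and a 24 h cosine and sine wave for each diet. The moderated F test of both wave coefficients called a gene rhythmic on a diet, and the F test that both coefficients are equal tested the difference between the diets. Amplitude is the distance from mean to peak on the log2 scale. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 in each test.

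The 40 gene lists covered metabolic pathways, the clock, stress responses, protein synthesis, immune responses and markers of other cell types. They were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, and their share among rhythmic genes with 2-sided Fisher exact tests. Median shifts in peak time and in amplitude were compared with 100 arrangements of the diet labels within each time, the real one included. For the clock lists, 100000 exchanges were drawn.

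Groups, tests, thresholds, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 12 highest and 12 lowest average differences among called genes with the same sign at all 6 times. It also named up to 4 called members with the smallest p per list (or the members with the smallest p where none passed), the 4 highest and 4 lowest called differences at each time, every measured core clock gene, and the 10 largest amplitudes on each diet. For the difference in rhythm it named the 10 smallest p with larger amplitude on each diet, and the 5 largest called shifts each way. Other genes named in the text were chosen after their values were seen.

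The fits were tested on simulated data with the real genes' means and spread. The simulated average diet effect was recovered for 80.6% of genes changed by 0.25 and for 100% of those changed by 0.5 on the log2 scale. At ZT0 alone 11.9%, 62.7% and 97.0% were recovered for changes of 0.25, 0.5 and 1. A simulated rhythm on chow of amplitude 0.25 was recovered for 76.1% of genes. The difference test recovered 52.2% of genes with amplitude 0.25 on chow and none on high fat diet. A peak 1 h earlier on high fat diet was called for 0% of simulated genes at amplitudes of 0.25 and 0.5 and for 33.3% at amplitude 1, although the median fitted shift was -0.978 h.

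Alternatives covered quantile normalization, median centring, the intensity filter, the mean of a gene's probe sets, the replicate number as a block, array weights, the variance prior, the offset, stricter thresholds, other rhythm tests, other list tests and leaving out each array in turn. Added after the data were seen were a fit without the 4 arrays of lowest quality weight, fits of the peak shift without each time, a test of the lists by exchanging diet labels, contrasts of lists between a time and the others, and fits of the heat shock list at ZT16 without each array of that time. Software was R 4.3.3 with limma 3.58.1 and data.table version 1.17.8, and Python 3.11.15 with matplotlib 3.10.9.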

Results

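Liver transcripts were measured in C57BL/6J mice, an inbred laboratory strain, that ate normal chow or a high fat diet and were 16 weeks old at harvest. Fat supplied 60% of the calories of the high fat diet, which was fed for 10 weeks. Livers were collected every 4 h at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, where Zeitgeber time (ZT) counts hours from lights on in a cycle with 12 h of light. Each of the 12 combinations of diet and time had 3 samples, 1 array each. Log2 values correlated between arrays of a group at 0.980 to 0.995 and between any 2 arrays at 0.952 or more. The median residual standard deviation of a gene was 0.14 on the log2 scale. The sex of the animals and other differences in composition between the diets are not given in the labels used here.

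The first comparison asked which liver genes differ between the diets over the whole day. Cyp2b9, a cytochrome P450, rose most on high fat diet, from a log2 intensity of 6.12 ± 1.02 (SD, n = 18) on chow to 9.99 ± 2.03 (SD, n = 18), a difference of 3.88 ± 0.39 (SE). Stap1, a signalling adaptor, rose from 5.51 ± 0.35 to 7.94 ± 0.57 (SD, n = 18 each), and Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 10.26 ± 0.20 to 12.07 ± 0.49. Rgs16, a regulator of G protein signalling, rose by 2.17 ± 0.28 and Mfsd2a, a lysophosphatidylcholine transporter, by 1.98 ± 0.18. The melatonin receptor gene Mtnr1a rose by 1.51 ± 0.07 and the steroid hydroxylase gene Cyp17a1 by 1.53 ± 0.16. The transporters Slc17a8 and Slc22a27 rose by 1.70 and 1.63, Themis by 1.67, 9030619P08Rik by 1.59 and Cyp2b13 by 1.56 ± 0.34. Adjusted p-values from limma ran from 4.53e-16 for Mtnr1a to 0.00117 for Cyp2b13. Each of these 12 genes had the same sign at 6 of 6 times, which the rule for naming them required.

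Cyp2b10, a cytochrome P450 induced by xenobiotics through CAR, showed the largest drop on high fat diet. Its log2 intensity went from 9.03 ± 0.86 to 5.87 ± 0.68 (SD, n = 18 each), a difference of -3.16 ± 0.14 (SE, limma adjusted p = 1.17e-16). Cyp2c55 fell by 2.24 ± 0.07 (adjusted p = 7.93e-21), Cyp3a44 by 2.13 ± 0.11 and Cyp3a16 by 1.35 ± 0.09. Adgrf1, an adhesion receptor, had a difference of -2.22 ± 0.19 and the carboxylesterase Ces2a of -1.36 ± 0.05. Csad, an enzyme of taurine synthesis, differed by -1.72 ± 0.12, Cyp26a1, which degrades retinoic acid, by -1.63 ± 0.19, and the citrate transporter Slc13a2 by -1.61 ± 0.08. Asns, which makes asparagine, differed by -1.198 ± 0.18, Gm16551 by -1.19 ± 0.13 and Cib3 by -1.13 ± 0.19. All 12 of these genes were lower at 6 of 6 times, again as the rule required. Cyp2b9, Cyp2b13 and Cyp2b10 have similar sequences, as do Cyp3a44 and Cyp3a16, and signal shared between their probe sets was not measured probe by probe.

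**Figure D1:**
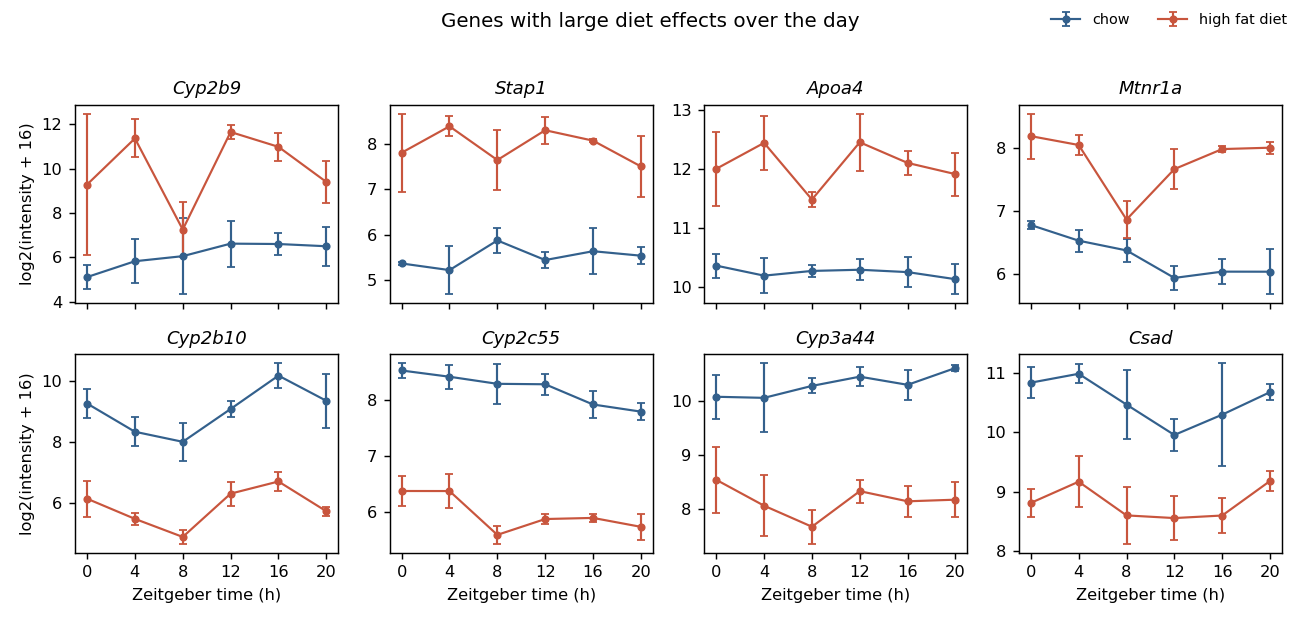
Log2(intensity + 16) of 8 genes against Zeitgeber time in h, on chow and on high fat diet. Points are means and bars SD of 3 samples; Cyp2b9, Stap1, Apoa4 and Mtnr1a lie higher and Cyp2b10, Cyp2c55, Cyp3a44 and Csad lower on high fat diet at each of the 6 times, by a margin that is smallest at ZT8 for Cyp2b9 (1.201) and Mtnr1a (0.49), where neither passed the threshold.

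Over all 13956 tested genes limma called 2937, of which 1570 were higher and 1367 lower on high fat diet. Quantile normalization turned the balance to 1455 higher and 1712 lower, and median centring to 1528 and 1609, so neither direction prevails. Most changes were small, with a median size of 0.18 on the log2 scale among called genes, and the median over all genes was 0.02. A difference of at least 2-fold was seen in 26 genes that rose and 18 that fell. The sign was the same at all 6 times for 1567 called genes, and 20 genes passed the threshold in the same direction at each time. At no single time did 1443 of the called genes pass. With a further requirement of 1.5-fold 139 genes were called, and 1818 at an adjusted p under 0.01.

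Genes of lipid use and storage were among those higher on high fat diet. Of 33 tested PPARA targets of fatty acid oxidation, 22 rose and 0 fell (24 and 0 adjusted over the list alone). They included the ketone body enzyme Bdh1 (0.58 ± 0.04), Cpt1a, which carries fatty acids into mitochondria (0.46 ± 0.03), Ppara itself (0.46 ± 0.05) and Etfdh (0.24 ± 0.03). Camera gave this list an adjusted p of 1.36e-14, and adjusted p = 0.1003 with an estimated correlation. Among 18 PPARG and lipid droplet genes 13 rose and 2 fell (13 and 2 adjusted over the list alone). Fabp2, a fatty acid binding protein, rose by 1.25 ± 0.06, the droplet coat protein Plin2 by 0.54 ± 0.04 and G0s2, an inhibitor of lipolysis, by 1.22 ± 0.13, beside Apoa4. The camera adjusted p was 3.52e-08 for this list, and adjusted p = 0.1003 with an estimated correlation. Markers of adipose tissue, some of which are in the droplet list, showed 3 of 9 genes higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.444). Cidec rose by 1.16, Fabp4 by 0.31 and Slc2a4 by 0.17, and Pnpla2 fell by 0.20. The call was lost in 22 of 46 alternatives for Slc2a4 and in 8 of 47 for Fabp4.

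Genes of fatty acid and triglyceride synthesis went both ways, with 10 of 27 higher and 3 lower (11 and 4 adjusted over the list alone). Insig2, which holds back SREBP processing, rose by 0.75 ± 0.06, the desaturase Fads2 by 0.39 ± 0.04, the glycolytic enzyme Pklr by 0.63 ± 0.07 and the elongase Elovl5 by 0.60 ± 0.08. The list's camera adjusted p was 0.00688, with adjusted p = 0.585 with an estimated correlation. Of 19 glycolysis and glycogen genes 11 rose and 2 fell (12 and 3 adjusted over the list alone), among them the fructose kinase Khk (0.50 ± 0.05), Ldha (0.33 ± 0.04) and Gckr (0.27 ± 0.04). That list had a camera adjusted p of 0.000200, and adjusted p = 0.1003 with an estimated correlation. Cholesterol synthesis moved the other way, with 12 of 21 genes lower and 0 higher (14 and 0 adjusted over the list alone). Pmvk fell by 0.47 ± 0.08, Tm7sf2 by 0.34 ± 0.06, Insig1 by 0.30 ± 0.06 and Tmem97 by 0.20 ± 0.04. Camera returned an adjusted p of 2.45e-08 for cholesterol synthesis, and adjusted p = 0.286 with an estimated correlation.

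The next lists hold genes of detoxification and sex-biased liver genes. Of 25 genes regulated by the xenobiotic receptors CAR and PXR, 16 fell and 4 rose (17 and 4 adjusted over the list alone), the 4 with the smallest p being Cyp2c55, Ces2a, Cyp2b10 and Cyp3a44. Camera gave an adjusted p of 1.02e-13, and adjusted p = 0.0770 with an estimated correlation. Of 27 glutathione and NRF2 target genes 13 fell and 3 rose (14 and 4 adjusted over the list alone). The glutathione transferases Gsta4, Gstm4 and Gstt2 fell by 0.88 ± 0.07, 0.59 ± 0.06 and 0.57 ± 0.06, and glutathione reductase Gsr fell by 0.29 ± 0.03. By camera the adjusted p was 3.45e-07, and adjusted p = 0.248 with an estimated correlation. Among 27 sex-biased or growth hormone-dependent liver genes 12 fell and 5 rose (12 and 6 adjusted over the list alone). The fatty acid hydroxylases Cyp4a12a and Cyp4a12b, which are higher in male liver, fell by 0.73 ± 0.05 and 0.78 ± 0.05, beside Cyp3a44 and Cyp3a16, which are higher in female liver. This list had a camera adjusted p of 0.000222, and adjusted p = 0.1003 with an estimated correlation. Several of these genes are shared with the CAR and PXR list.

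Genes of the ribosome and of protein folding were tested in 3 lists. Ribosomal protein genes fell in 27 of 34 cases and rose in 0 (31 and 0 adjusted over the list alone), including Rpl13 (-0.30 ± 0.04), Rps14 (-0.26 ± 0.04), Rplp1 (-0.31 ± 0.05) and Rps18 (-0.29 ± 0.05). The camera adjusted p was 4.98e-18, and adjusted p = 0.0770 with an estimated correlation. Of 32 ribosome biogenesis genes 14 fell and 0 rose (19 and 0 adjusted over the list alone), with Nop56 at -0.29 ± 0.04, Gnl3 at -0.29 ± 0.05, Bop1 at -0.22 ± 0.04 and Mybbp1a at -0.22 ± 0.04. That list had a camera adjusted p of 7.72e-09, and adjusted p = 0.1003 with an estimated correlation. In the unfolded protein response 9 of 31 genes fell and 3 rose (14 and 3 adjusted over the list alone). Asns, Sdf2l1 (-0.59 ± 0.12) and the chaperone Hyou1 (-0.35 ± 0.06) were lower and Sesn2 (0.26 ± 0.06) was higher. Camera returned an adjusted p of 0.000170, and adjusted p = 0.318 with an estimated correlation.

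Camera called 4 further lists as lower, each of which lost the camera call after quantile normalization, with the direction kept. Proteasome genes fell in 6 of 31 cases, among them Psmb4 (-0.20 ± 0.05) and Psmb6 (-0.20 ± 0.05), and rose in 0 (8 and 0 adjusted over the list alone). Their camera adjusted p was 0.00230, and adjusted p = 0.314 with an estimated correlation. Subunits of oxidative phosphorylation fell in 5 of 40 cases and rose in 0 (3 and 0 adjusted over the list alone), with Atp5o at -0.17 ± 0.04 and Cox4i1 at -0.14 ± 0.04. By camera the adjusted p was 0.00424, and adjusted p = 0.498 with an estimated correlation. In purine and pyrimidine metabolism 11 of 30 genes fell and 6 rose (13 and 7 adjusted over the list alone), with Aprt at -0.60 ± 0.05 and Upp2 at -0.54 ± 0.05. Camera gave 0.0222, and adjusted p = 0.314 with an estimated correlation. In the urea cycle and amino acid catabolism list 9 of 30 genes fell and 5 rose (10 and 5 adjusted over the list alone). Its members with the smallest p were Csad, Ddc (-0.68 ± 0.07), Agxt2 (0.23 ± 0.03) and Ivd (-0.24 ± 0.04), of which Csad and Ddc are amino acid decarboxylases outside the urea cycle. The camera adjusted p was 0.0323, and adjusted p = 0.568 with an estimated correlation.

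Lists of immune genes and macrophage markers were called as higher. Interferon-stimulated genes rose in 16 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone), with Ifit1 at 0.78 ± 0.07, Gbp3 at 0.69 ± 0.07, Ifi27 at 0.51 ± 0.06 and Usp18 at 0.51 ± 0.06. Camera returned an adjusted p of 1.10e-10, and adjusted p = 0.0770 with an estimated correlation. Beside them, markers of Kupffer cells and macrophages rose in 13 of 21 cases and fell in 1 (16 and 1 adjusted over the list alone), with a median difference of 0.27. Mpeg1 rose by 0.57 ± 0.07, Cd5l by 0.56 ± 0.10 and Lgals3 by 0.24 ± 0.06, and Cd9 fell by 0.45 ± 0.06. Camera gave 0.000104, and adjusted p = 0.318 with an estimated correlation. Of 21 cell cycle genes 8 rose and 0 fell (10 and 0 adjusted over the list alone), with Rrm2 at 0.58 ± 0.10 and Mcm4 at 0.24 ± 0.05, in the same samples as the higher macrophage markers. By camera the adjusted p was 0.00214, and adjusted p = 0.369 with an estimated correlation. Of 6 neutrophil genes 1 rose (2 adjusted over the list alone), Lcn2 by 1.24 ± 0.16, which hepatocytes also make in acute phase responses. The camera adjusted p was 0.0278, and adjusted p = 0.314 with an estimated correlation, and the call was lost after quantile normalization.

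Markers of other cell types were tested in 7 further lists, averaged over the day, where 1570 of all 13956 tested genes rose and 1367 fell. Among T, NK and B cell genes 3 of 10 rose (3 adjusted over the list alone), Cd4 by 0.30, Ptprc by 0.22 and Ccl5 by 0.21. Stellate cell and matrix genes rose in 4 of 24 cases (1 adjusted over the list alone), Reln by 0.28, Lrat by 0.24, Bgn by 0.20 and Dcn by 0.19. These small rises sit near the threshold, and over 47 alternatives the call was lost in 23 for Dcn, 21 for Bgn, 17 for Ptprc and 12 for Lrat. Of 20 sinusoidal endothelial genes 1 fell, Tie1, at -0.16, and of 6 bile duct genes 1 rose, Pkhd1, at 0.14 (1 and 0 adjusted over the lists alone), a call that 24 of the alternatives lost. In the exocrine pancreas and gut list Cela1 rose by 0.18, as 1 of 8 genes. No gene passed among 3 red blood cell and 11 muscle genes, where Alas2 stood at -0.07 and Tnni2 at 0.16. Camera called none of these 7 lists, with adjusted p-values of 0.232, 0.141, 0.554, 0.725, 0.889, 0.766 and 0.615 in the order T, NK and B cell, stellate, endothelial, bile duct, pancreas and gut, red blood cell and muscle. Without the 4 arrays of lowest weight, an alternative chosen after seeing the data, it called the T, NK and B cell list (0.0454) and the stellate list (0.0300).

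Several metabolic lists held changes in both directions without a camera call. For comparison, 1570 of all 13956 tested genes rose and 1367 fell. Counts near those shares do not set a list apart from other genes. In bile acid synthesis and transport 6 of 24 genes rose and 6 fell (7 and 6 adjusted over the list alone), with the phospholipid exporter Abcb4 at 0.37 ± 0.03 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.39 ± 0.06. Acute phase genes rose in 7 of 30 cases and fell in 4 (7 and 8 adjusted over the list alone), with Saa2 at 1.15 ± 0.15 and Orm1 at -0.32 ± 0.04, beside Lcn2. In NAD synthesis 4 of 20 genes fell and 1 rose (4 and 1 adjusted over the list alone), with Acmsd at -0.99 ± 0.10 and Afmid at -0.43 ± 0.04. In insulin signalling 7 of 25 fell and 3 rose (7 and 3 adjusted over the list alone), with Igfbp2 at -0.96 ± 0.10, Irs2 at -0.39 ± 0.06 and Pik3r1 at 0.30 ± 0.05. One-carbon metabolism had 6 of 25 higher and 4 lower, with Cth at -0.38, lipoprotein metabolism 3 of 17 higher and 2 lower, with Apom at -0.44, and gluconeogenesis 3 of 16 higher and 2 lower, with G6pc at 0.30. In the TCA cycle 3 of 20 rose and 4 fell, with Idh2 at -0.30, and of 22 heat shock genes 2 rose and 4 fell, with Hspb1 at -0.53. Of 17 hepatocyte identity genes Foxa3 (-0.24) and Hnf4a (-0.13) fell, and of 3 major urinary protein genes Mup21 (0.30) rose, a call lost in 11 of 47 alternatives. Adjusted over the list alone, higher and lower genes numbered 6 and 4 in one-carbon metabolism, 4 and 2 in lipoprotein metabolism, 3 and 2 in gluconeogenesis, 5 and 4 in the TCA cycle, 2 and 4 among heat shock genes, 0 and 2 for hepatocyte identity and 3 and 0 among major urinary proteins. Of the clock lists, 1 of 15 core genes rose, Bhlhe40 (0.38 ± 0.08), and 1 fell, Bhlhe41 (-0.42 ± 0.07). Among 16 clock output genes 3 rose and 2 fell, with Upp2 at -0.54, Tspan4 at -0.36, Hlf at 0.26 and Wee1 at 0.26, the last a call lost in 11 of 47 alternatives. The clock lists alone gave 1 and 1 core genes and 3 and 3 output genes.

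**Figure D2:**
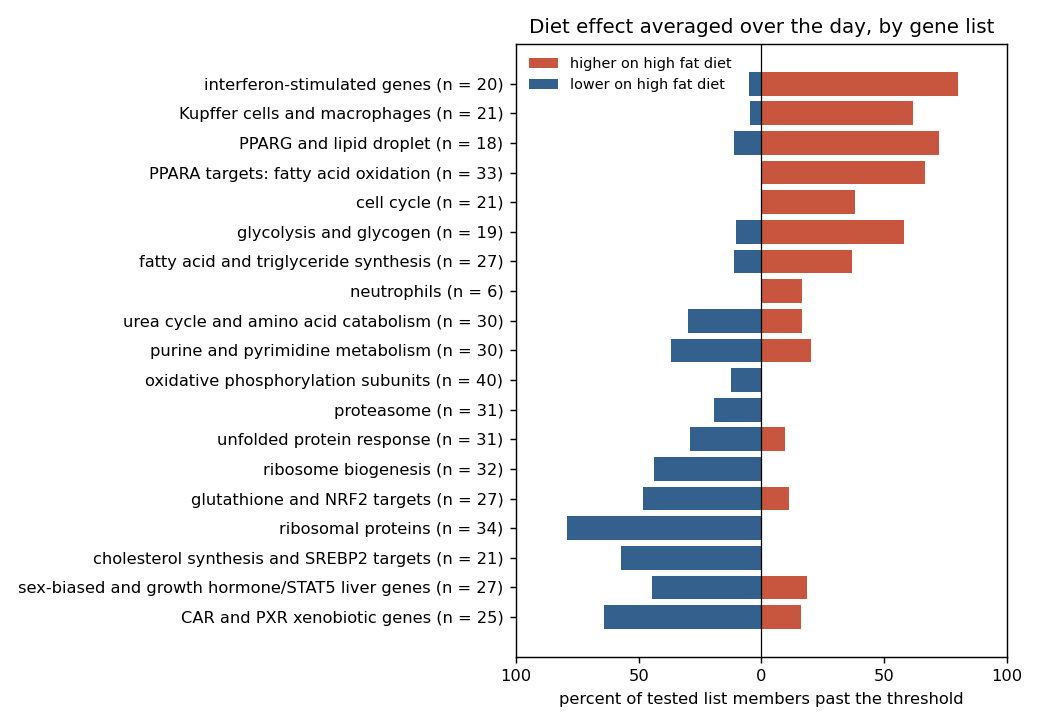
Percent of the tested members of each gene list that were higher (to the right) or lower (to the left) on high fat diet averaged over the day, for the 19 lists called by camera, ordered by median log2 difference. Ribosomal proteins have 27 of 34 members lower and interferon-stimulated genes 16 of 20 higher.

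Camera thus called 8 lists as higher and 11 as lower of 40 at the preset correlation, and 0 of them with an estimated correlation, while fry, a rotation test of whether a list's genes move on balance in 1 direction, called 22. Exchanging the diet labels within times gave a median of 8 lists by preset camera and up to 19, so the preset test calls lists readily in these samples.

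The second comparison asked at which times of day the diets differ, and the highest and lowest differences below are those among called genes. At ZT0 the 4 highest differences were in Cyp2b9 (4.18), Rgs16 (2.78), Stap1 (2.43) and Mfsd2a (2.15), and the 4 lowest in Cyp2b10 (-3.12), Cyp2c55 (-2.16), Cyp26a1 (-2.05) and Csad (-2.03). At ZT4 Cyp2b9 rose by 5.55, Mfsd2a by 3.88, Rgs16 by 3.87 and Cyp2a22 by 3.17, and Cyp2b10, Adgrf1, Cib3 and Serpina4-ps1 stood at -2.86, -2.67, -2.29 and -2.07. At ZT8 Mfsd2a and Stap1 both rose by 1.77, G0s2 by 1.44 and Ppp1r3b, a glycogen-targeting subunit, by 1.26. Cyp2b10 (-3.12), Cyp2c55 (-2.71), Cyp3a44 (-2.60) and Cyp26a1 (-2.06) fell most at ZT8. At ZT12 Cyp2b9 rose by 5.04, Stap1 by 2.85, Slc22a27 by 2.64 and Cyp17a1 by 2.47, with Adgrf1 at -3.22, Cyp2b10 at -2.78, Cyp2c55 at -2.42 and Cyp26a1 at -2.35. At ZT16 Cyp2b9 (4.39), Stap1 (2.43), Cyp17a1 (2.12) and Mtnr1a (1.95) were highest and Cyp2b10 (-3.47), Adgrf1 (-2.51), Cyp3a44 (-2.15) and Cyp2c55 (-2.03) lowest. At ZT20 Slc17a8 rose by 2.34, the arrestin-domain gene Arrdc3 by 2.16, Mtnr1a by 1.97 and Stap1 by 1.96, with Cyp2b10 at -3.62, Cyp3a44 at -2.43, Adgrf1 at -2.30 and Cyp2c55 at -2.07. The limma adjusted p-values of these genes ran from 3.34e-12 (Cyp2c55 at ZT8) to 0.0414 (Mfsd2a at ZT8), with 3 samples per group.

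Some of these values depend on the processing or on 1 array. Over 47 alternatives Cyp2b9 at ZT0 ranged from 2.42 to 5.53 and lost its call in 2, Rgs16 at ZT0 ranged from 1.74 to 3.71 and lost it in 3, and Mfsd2a at ZT0 ranged from 1.42 to 2.90 and kept it. At ZT8 the call was lost in 12 for Mfsd2a, in 6 for Cyp26a1 and in 2 for G0s2, and Cyp2b10 ranged from -4.08 to -1.98. Calls were also lost for Cyp2a22 (3) and Serpina4-ps1 (2) at ZT4, Cyp2b9 (2) at ZT16 and Adgrf1 (1) at ZT20, and Stap1 at ZT20 ranged from 1.29 to 2.40 over 46 alternatives.

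Gene groups also differed by diet at single times. PPARA targets had 17 of 33 members higher at ZT4 (camera adjusted p = 4.28e-20; adjusted p = 0.160 with an estimated correlation) and 13 at ZT12 (2.94e-12; adjusted p = 0.144 with an estimated correlation). At ZT8 1 of the 33 rose. PPARG and lipid droplet genes rose in 8 of 18 cases at ZT12 and in 7 at ZT4. Their camera adjusted p at ZT12 was 1.65e-11, and adjusted p = 0.0660 with an estimated correlation. Of 25 CAR and PXR genes 15 fell at ZT12 (camera adjusted p = 6.15e-12; adjusted p = 0.0660 with an estimated correlation) and 8 each at ZT0, ZT8 and ZT20. Macrophage markers rose in 9 of 21 cases at ZT0, with a median difference of 0.64, and in 3 at ZT12. Camera gave 9.94e-07 for them at ZT0, and adjusted p = 0.348 with an estimated correlation. Core clock genes went both ways over the day, with 3 of 15 higher and 0 lower at ZT0, 4 higher and 1 lower at ZT4, and 0 higher and 3 lower at ZT20. Camera gave the core clock list adjusted p-values of 0.104, 0.671 and 0.00156 at these times, and at ZT20 adjusted p = 0.203 with an estimated correlation. At ZT8 camera called markers of sinusoidal endothelium as lower, with a median of -0.30 and 0 single genes past the threshold (7.27e-06; adjusted p = 0.562 with an estimated correlation). Muscle and bile duct markers were called as higher at ZT8 with medians of 0.14 and 0.19 (0.0319 and 0.0480; adjusted p = 0.562 and 0.529 with an estimated correlation). Preset camera called more marker lists as higher: muscle at ZT0 (0.0359), stellate (0.00935) and neutrophil (0.0288) at ZT4. Neutrophil genes were also called as higher at ZT8 (0.0402) and ZT12 (0.0341), and T, NK and B cell genes at ZT12 (0.0125). Muscle markers were called as lower at ZT20 (0.0422). With an estimated correlation the adjusted p of these was 0.173 or more. These time contrasts do not test whether a group's effect differs between times.

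By limma, 993 genes were called at ZT0 (470 higher, 523 lower), 515 at ZT4 (319 and 196), 108 at ZT8 (39 and 69), 759 at ZT12 (345 and 414), 310 at ZT16 (146 and 164) and 285 at ZT20 (173 and 112). Single arrays moved every one of these counts. At ZT0 501 genes were called without chow replicate 2, 270 without chow replicate 3, 377 without high fat diet replicate 1 and 436 without high fat diet replicate 2. At ZT4 292 were called without chow replicate 2, 258 without high fat diet replicate 1 and 327 without high fat diet replicate 3. At ZT8 it was 56 without chow replicate 2, 70 without chow replicate 3, 54 without high fat diet replicate 1 and 68 without high fat diet replicate 2. At ZT12 it was 487 without chow replicate 1, 291 without chow replicate 2, 453 without high fat diet replicate 2 and 454 without high fat diet replicate 3. At ZT16 it was 127 without chow replicate 2, 180 without chow replicate 3, 96 without high fat diet replicate 2 and 158 without high fat diet replicate 3. At ZT20 it was 121 without chow replicate 3, 182 without high fat diet replicate 2 and 128 without high fat diet replicate 3. Array weights raised the count at ZT8 to 1716, so the order of the times by number of genes is not fixed.

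The third comparison asked which genes follow a 24 h rhythm on each diet. Among genes called rhythmic on chow, the largest amplitudes belonged to the clock repressor Ciart (2.505 ± 0.16, SE), the nuclear receptor Nr1d1 (2.31 ± 0.17) and the clock output factor Dbp (2.24 ± 0.12). Mfsd2a (1.92), Rgs16 (1.86), the deubiquitinase Usp2 (1.74), Arntl (1.61), Per3 (1.46), Nr1d2 (1.32) and the phosphatidate phosphatase Lpin1 (1.30) followed. Among those called on high fat diet Ciart (2.22 ± 0.16), Dbp (2.05 ± 0.12) and Nr1d1 (1.95 ± 0.17) had the largest amplitudes. They were followed by Usp2 (1.70), Arntl (1.54), Rgs16 (1.52), Per3 (1.33), Noct (1.29), the choline kinase Chka (1.27) and Per1 (1.204). Each of these genes passed the limma F test on both diets, with adjusted p-values up to 0.00484 (Mfsd2a on high fat diet).

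Among gene groups, all 16 tested clock output genes and 12 of 15 core clock genes were rhythmic on chow, as on high fat diet (Fisher exact adjusted p = 4.16e-10 and 2.83e-05 on chow, 1.80e-14 and 2.07e-08 on high fat diet). Bile acid genes were rhythmic in 14 of 24 cases on chow and 10 on high fat diet, and heat shock genes in 13 of 22 and 10. Glycolysis and glycogen genes were rhythmic in 10 of 19 cases on chow and 6 on high fat diet. These 5 lists were enriched on both diets, with Fisher adjusted p-values up to 0.0161 on chow and 0.0498 on high fat diet. On high fat diet 6 further lists passed, with 10 of 16 gluconeogenesis genes (adjusted p = 1.49e-05), 14 of 31 unfolded protein response genes (1.61e-05), 10 of 25 insulin signalling genes (0.00102), 8 of 20 interferon-stimulated genes (0.00401), 7 of 20 NAD synthesis genes (0.0185) and 8 of 30 purine and pyrimidine genes (0.0498). On chow those lists held 6, 12, 10, 8, 7 and 10 rhythmic genes. Ribosomal protein genes were rhythmic less than the other tested genes on chow, in 1 of 34 cases (Fisher adjusted p = 0.0364), and in 0 on high fat diet (0.0809). The Fisher tests take genes as independent, which they are not. With adjustment over the list alone, 12 core clock genes were rhythmic on chow and 14 on high fat diet.

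In all, 2879 genes (20.6%) were rhythmic on chow and 1540 (11%) on high fat diet by limma. Both calls were met by 1145 genes, against 318 if the lists were independent. The median amplitude of called genes was 0.21 on chow and 0.22 on high fat diet. On chow 844 of the rhythmic genes peaked within 2 h of ZT8 and 583 around ZT4, against 262 and 228 on high fat diet, while 377 and 313 peaked around ZT12. A rank test of the JTK type called 2276 and 1147 genes. The calls of 1734 genes on chow alone and 395 on high fat diet alone are not shown to differ, because 0 of them passed the test of the difference below. An F test over the 6 time means, which needs no 24 h wave, called 2926 and 2340 genes, a smaller gap. Array weights gave 2802 on high fat diet, and their count on chow is not given here. Whether the gap holds with array weights is therefore left open.

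Core clock genes peaked earlier on high fat diet. Arntl, the partner of Clock, had amplitudes of 1.61 and 1.54 and peaked at ZT 22.1 on chow and 20.5 on high fat diet, a shift of -1.64 ± 0.39 h (SE). The repressor Nr1d1 moved from 6.80 to 5.17 (-1.63 ± 0.42 h) and Ciart from 11.4 to 9.77 (-1.62 ± 0.36 h). Per3 moved by -1.62 ± 0.41 h, Clock by -1.96 ± 0.59 h, Nr1d2 by -1.58 ± 0.56 h and Cry2 by -1.52 ± 0.88 h. Per2 peaked at 14.6 on chow and 11.8 on high fat diet, the largest shift of the list at -2.79 ± 0.46 h. Cry1 moved by -1.11 ± 0.34 h, Bhlhe40 by -1.41 ± 0.99 h, Bhlhe41 by -1.02 ± 0.75 h and Per1, from 12.2 to 11.9, by -0.23 ± 0.66 h, a shift that turned to 0.12 h without chow ZT20 replicate 1. Rora, Csnk1d and Csnk1e were not called rhythmic on either diet. All 12 rhythmic core genes were earlier, with a median shift of -1.60 h (permutation p = 1e-05, two-sided, the smallest that 100000 exchanges of diet labels can give). All 16 clock output genes were earlier too, with a median of -1.39 h and the same smallest p. The median log2 amplitude ratio of high fat diet to chow was -0.14 for the core list (permutation p = 0.192) and -0.13 for the output list (p = 0.199), and neither passed.

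**Figure D3:**
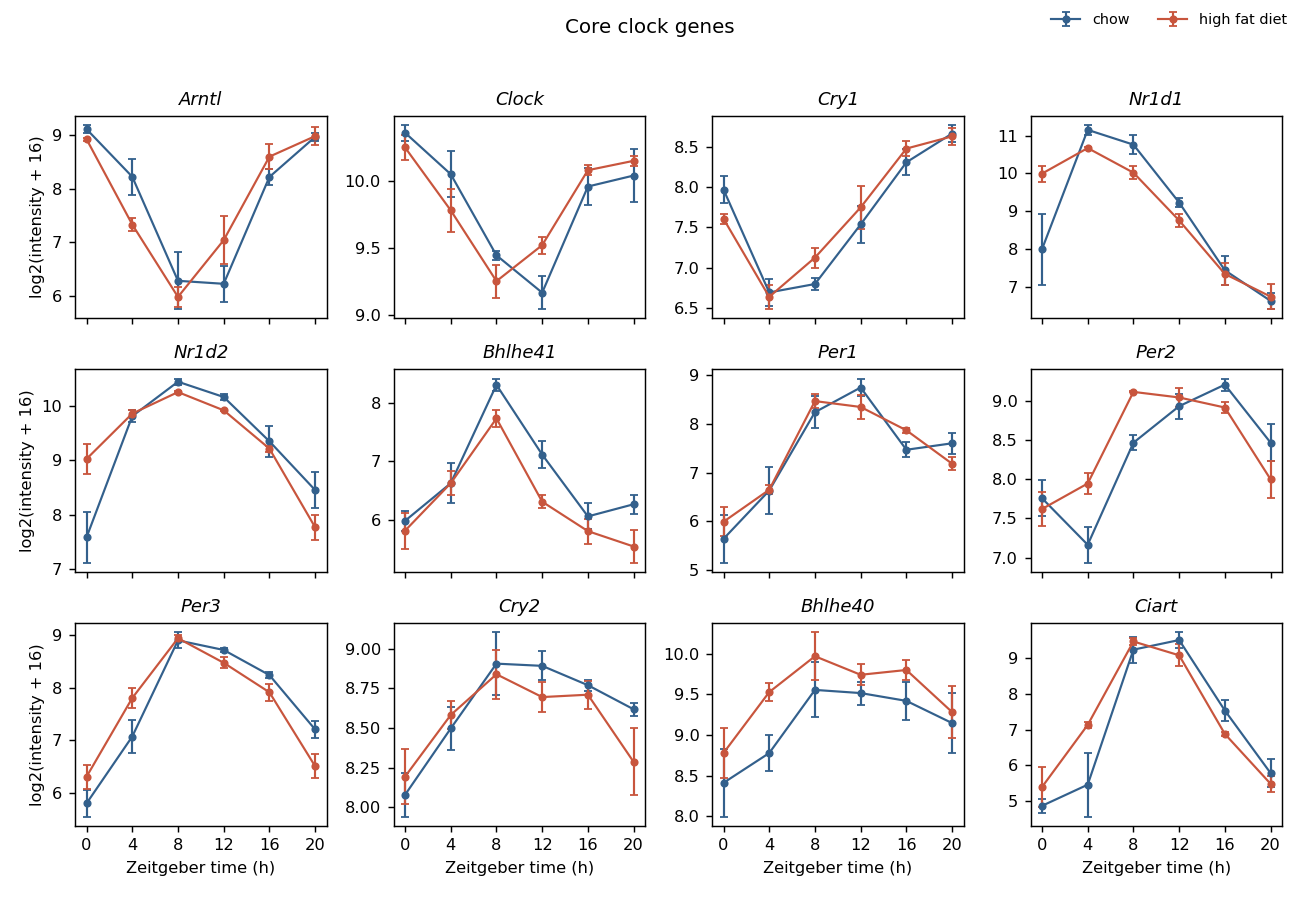
Log2(intensity + 16) of the 12 rhythmic core clock genes against Zeitgeber time in h on chow and on high fat diet, as mean and SD of 3 samples. The high fat diet curves run ahead of the chow curves, with shifts in fitted peak from -2.79 h (Per2) to -0.23 h (Per1).

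The fourth comparison asked whether the rhythm itself differs between the diets. By the limma test of both wave coefficients 4 genes passed. Fpgs, which adds glutamates to folate, peaked at ZT 23.1 on chow and 18.7 on high fat diet, a shift of -4.39 ± 0.64 h (SE, adjusted p = 0.00585). Elovl3, a fatty acid elongase, shifted by -3.24 ± 0.48 h (adjusted p = 0.00586), Per2 by -2.79 ± 0.46 h (0.0137) and Asap2 by -1.996 ± 0.37 h (0.0137). Amplitudes on chow and high fat diet were 0.42 and 0.33 for Fpgs, 1.00 and 1.08 for Elovl3, 0.94 and 0.82 for Per2 and 0.73 and 0.57 for Asap2.

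Genes that came next did not pass and are given as values. With a larger amplitude on chow these were Rpp38 (0.27 on chow, 0.13 on high fat diet), Amt (0.40 and 0.20), Nek7 (0.17 and 0.11), Dedd2 (0.44 and 0.11), Rnf125 (0.67 and 0.63), Lrp5 (0.38 and 0.28) and Obp2a (0.66 and 0.52), with limma adjusted p-values from 0.0632 to 0.0844. With a larger amplitude on high fat diet they were Hacl1 (0.43 on chow, 0.54 on high fat diet), Cyp7a1 (0.16 and 0.71), Slc49a4 (0.20 and 0.22), Ppp1r15a (0.134 and 0.135), Clpx (0.91 and 1.02), Pdia3 (0.12 and 0.22), Tab2 (0.24 and 0.29), Mcu (0.37 and 0.39) and Cyp4a12a (0.04 and 0.34), with adjusted p-values from 0.0632 to 0.181. Adjusted over the list alone, 9 of 15 core clock genes and 6 of 16 clock output genes passed the difference test, against 1 (Per2) and 0 over all genes.

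At an unadjusted p under 0.05, 1161 genes passed the difference test, and 43 passed when adjusted only over genes rhythmic on a diet. The count of 4 was 7 without chow ZT0 replicate 3, 11 without high fat diet ZT4 replicate 1, 9 without chow ZT16 replicate 1 and 7 without chow ZT20 replicate 2. It was 11 after quantile normalization, 8 after median centring, 185 with array weights, 2 at an adjusted p under 0.01 and 1 without the 4 arrays of lowest weight, an alternative chosen after seeing the data. The interaction of diet and time over the 6 time means, with no wave assumed, called 88 genes by limma, 68 of them rhythmic on a diet and all 4 above among them. Among the 88, core clock genes were 6 of 15 (Fisher adjusted p = 1.01e-08), fatty acid synthesis genes 3 of 27 (0.00847), sex-biased genes 3 of 27 (0.00847) and gluconeogenesis genes 2 of 16 (0.0445).

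The fifth comparison took the 1145 genes rhythmic on both diets. Peaks were earlier on high fat diet for 875 of them (76.4%) and later for 270. The median shift was -1.01 h, with quartiles at -1.91 and -0.07 h. By the time of the chow peak the median shift was -1.76 h around ZT0, -1.11 h around ZT4, -0.73 h around ZT8, -0.41 h around ZT12, -1.27 h around ZT16 and -1.04 h around ZT20. Among lists with at least 5 such genes, the clock lists aside, the farthest medians were -2.38 h for 5 fatty acid synthesis genes, -1.72 h for 5 urea cycle and amino acid genes, -1.69 h for 7 purine and pyrimidine genes, and 2.64 h for 7 unfolded protein response genes, 1 of which was earlier. Of 100 arrangements of the diet labels within times, the real one gave the median shift farthest from 0, and the next gave -0.91 h. The shifts of lists were not tested, apart from the clock lists.

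Amplitudes were smaller on high fat diet for 690 of the 1145 genes (60.3%). The median log2 ratio of high fat diet to chow was -0.11, the farthest from 0 of 100 arrangements of the diet labels, of which the next gave -0.09. Of lists with at least 5 genes rhythmic on both diets, glycolysis and glycogen (5) had a median log2 ratio of -0.70, heat shock (9) of -0.47, PPARA targets (7) of -0.44 and the unfolded protein response (7) of 0.48. The median over the 1145 genes depended on single arrays, being -0.0608 without high fat diet ZT4 replicate 1 and -0.0603 without replicate 3 of that group. Without high fat diet ZT16 replicates 1, 2 and 3 in turn it was -0.0736, -0.0742 and -0.0712, and without high fat diet ZT20 replicates 1, 2 and 3 it was -0.0616, -0.0686 and -0.0580. It was -0.0487 for genes called at an adjusted p under 0.001 on both diets, -0.175 with array weights and -0.163 without the 4 arrays of lowest weight.

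**Figure D4:**
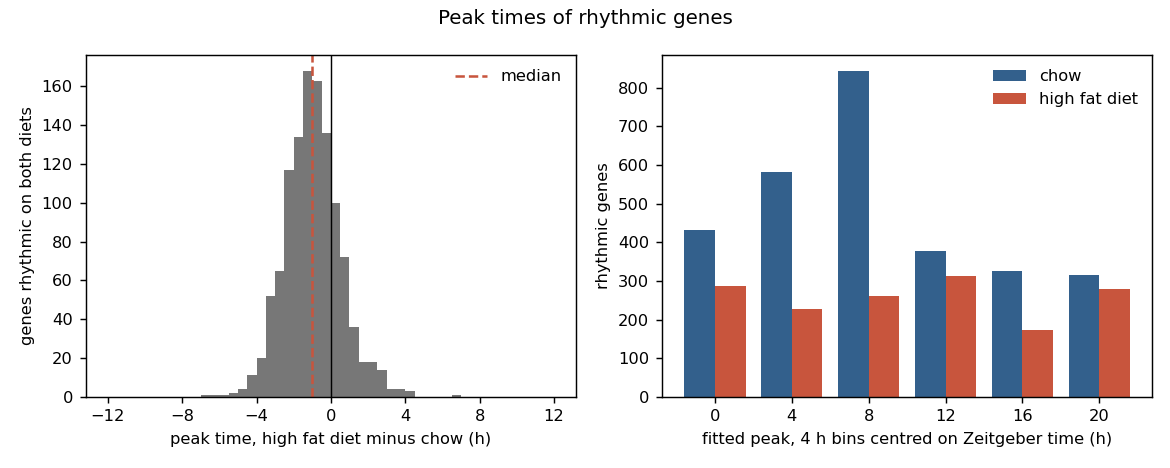
Left, number of genes rhythmic on both diets by the difference in fitted peak time, high fat diet minus chow, in bins of 0.5 h, with the median of -1.01 h dashed. Right, number of rhythmic genes by fitted peak in 4 h bins centred on each Zeitgeber time, on chow and on high fat diet, with 844 chow genes in the bin at ZT8.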

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

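The tests of the interaction, of the difference in rhythm, of the gap in rhythmic genes under label exchange, of the 24 h wave's share and of the sex of the animals were chosen before their results were seen. The other label exchanges and permutations, the tests of probe sets outside the comparisons and the remaining tests of the 3 patterns were chosen only after the result was seen.

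Diet effects that change with the time of day were found in 88 genes by the limma interaction of diet and time, and a difference in rhythm in 4. The genes given below are those of the 88 that the naming rule had picked, which takes in every measured core clock gene. They do not rank all 88. Elovl3 (adjusted p = 3.74e-06) was lower on high fat diet by day and higher by night, with log2 differences from -0.85 at ZT8 to 1.05 at ZT12. Dbp and Nr1d2 (7.57e-05 each) were higher at ZT0, by 1.24 and 1.44, and stood at -0.50 and -0.68 at ZT20. Nr1d1 (0.000477) ran from 2.00 at ZT0 to -0.74 at ZT8, Per2 (0.000477) from 0.78 at ZT4 to -0.47 at ZT20, Fpgs (0.000477) from -0.29 at ZT4 to 0.55 at ZT12 and Insig2 (0.000477) from -0.11 at ZT8 to 1.42 at ZT12. Per3 (0.000552) ran from 0.73 at ZT4 to -0.70 at ZT20, Ciart (0.00967) from 1.68 at ZT4 to -0.66 at ZT16 and Arntl (0.0155) from -0.89 at ZT4 to 0.82 at ZT12.

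Among metabolic genes, Ppp1r3b (0.00157) had its largest difference at ZT8 (1.26), Arrdc3 (0.0036) at ZT20 (2.16) and G6pc (0.0178) at ZT8 (0.86). Cyp7a1 (0.00436) stood at -1.20 at ZT0 and 0.24 at ZT8. Mtnr1a (0.0065) differed least at ZT8 (0.49), and Cyp4a12a (0.00841) ran from -0.32 at ZT0 to -1.24 at ZT16, with its relative Cyp4a12b at an adjusted p of 0.019. Interaction adjusted p-values of the other genes named for rhythm were 0.00118 for Hacl1, 0.00967 for Asap2, 0.0128 for Rpp38, 0.014 for Lrp5, 0.0195 for Clpx and for Dedd2, 0.0249 for Rnf125 and 0.0307 for Slc49a4.

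Probe sets outside the gene-level comparisons also differed by diet on average. Of 1029 bright enough probe sets that name several genes 325 passed (31.6%; 116 higher, 209 lower), and of 6167 without a gene name here 322 passed (5.22%; 182 higher, 140 lower). No group held 4 to 10 samples, so single outlying samples were not sought.

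Diet labels were exchanged within times in 100 arrangements, the real one included. As many genes with an average diet effect were called in 1 of 100 (2937, against at most 22 in the others). At single times the real count was matched in 1 of 10 splits of the 6 samples at each of ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, where the others gave at most 1 gene, and 10 splits are too few for a p under 0.05. With times permuted, as many rhythmic genes were called in 1 of 100 on chow (at most 260 in the others) and in 1 of 100 on high fat diet (at most 30). For the 4 genes with a difference in rhythm, 2 of 100 arrangements gave as many, another giving 18. For the 88 interaction genes it was 2 of 100, another giving 242. Such counts point to structure among the samples, which includes diet here: the arrangement with 242 kept the true labels at 2 of 6 times and that with 18 at 3 of 6. Kept labels alone do not set the count, as other arrangements that kept them at 2 of 6 times gave 0 or 10 interaction genes. An arrangement with labels kept at 1 time and fully swapped at 1 gave 59. Whether anything other than diet contributes was not tested. The median peak shift and the median amplitude ratio were matched in 1 of 100 each. For the 19 gene lists it was 2 of 100, another also giving 19.

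The first pattern weighed is the earlier peaks on high fat diet, by -1.01 h in the median. Further scaling did not remove it, as the shift was at least -0.956 h after quantile normalization or median centring. The farthest other arrangement of labels gave -0.911 h, on values without that scaling. The normalization between arrays before deposit is not given, so its part could not be tested. Leaving out any 1 time of harvest left at least -0.804 h, which argues against a single time as the whole source. Label exchanges over all times reached -0.911 h, and none were run on the fits without a time. Those fits therefore do not show that the remaining shift exceeds that of exchanged labels. A fixed offset in clock time between the diets at harvest could not be told apart from a shift of the clock, because the shift varied by 1.35 h over bins of peak time and by up to 2.9 h under exchanged labels. Diet, the factor that differs between the groups compared at each harvest time, remains open as the biological explanation, and feeding times are not given in the labels.

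The second pattern is the smaller number of rhythmic genes on high fat diet, a gap of 1339. As large a gap came up in 2 of 100 arrangements of the diet labels, another giving 1416. Spread between animals was not larger on high fat diet, with a ratio of 0.941 to chow. The rhythm fit shares 1 spread per gene between the diets, so this ratio cannot decide on spread as a source of the gap. The gap was at least 930 with any 1 array left out. It was smaller by the F test over the 6 time means, which called 2926 genes on chow and 2340 on high fat diet. Array weights raised the count on high fat diet, and without their count on chow the gap under weights is left open. The share of variance between times held by a 24 h wave was 0.661 on high fat diet and 0.785 on chow, a difference of -0.124. As low a difference arose in 11 of 100 exchanges, so profiles with another shape on high fat diet remain open.

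The third pattern is the opposite movement of related cytochrome genes. The mean of 3 Y-linked genes lay between 8.53 and 8.91 over all 36 arrays, a range of 0.377, which argues against animals of both sexes as the source. Xist, whose level also differs between the sexes, lay between 4.53 and 5.52, below the filter of 6.11. Together these values argue against female animals on any array. Signal shared between related probe sets would move Cyp2b9 and Cyp2b10 alike, so it cannot alone give their opposite signs. Those signs are how the pattern was chosen, so Cyp2b10 at -3.16 is no separate test, and partial sharing is not excluded. Sharing also stays open for Cyp2b13 with Cyp2b9 and Cyp3a16 with Cyp3a44, pairs that moved alike by at least 1.35. A turn from the male towards the female pattern stays open for Cyp2b9, Cyp2b13 and Cyp17a1, which were set apart after their values were seen. Male-biased genes had a median of -0.417 (1 of 13 higher, 8 lower) and female-biased genes of 0.553 (4 of 8 higher, 2 lower). The female-biased genes include members that define this pattern, so their median is no separate evidence. The turn would raise Cyp3a44 and Cyp3a16 and so would not account for falls in these genes, the smaller of which was -1.35. Their probe sets were bright on chow, at 10.29 for Cyp3a44 and 8.02 for Cyp3a16. Signal in them from other Cyp3a genes was not measured, so the falls are not shown to come from these genes. Those falls are part of the pattern as chosen. Diet components other than fat were not tested.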

How the results depend on the processing

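The fits without the 4 arrays of lowest weight or without each time, and the exchange test of lists, were chosen only after the result was seen. Counts at single times and of genes that differ in rhythm moved under many settings, and the median peak shift stayed negative in every setting. Genes with a difference in rhythm numbered 11 after quantile normalization, 8 after median centring, 88 by the interaction over time means and 43 among genes rhythmic on a diet. With array weights the counts were 1082 at ZT4, 1716 at ZT8, 1205 at ZT12, 1336 at ZT16 and 821 at ZT20, 2802 rhythmic on high fat diet and 185 different in rhythm, with an amplitude ratio of -0.175. At an adjusted p under 0.01 they were 1818 on average, 204, 221, 52, 296, 101 and 110 from ZT0 to ZT20, 1711 rhythmic on chow, 855 on high fat diet and 2 different. A 1.5-fold minimum left 139 on average, and the same minimum from peak to trough 682 on chow and 454 on high fat diet. Only the 6 samples of a time gave 285 at ZT0, 229 at ZT4, 193 at ZT16 and 154 at ZT20. The F test over 6 means called 2340 on high fat diet. The amplitude ratio was -0.0487 at an adjusted p under 0.001. Estimated correlation left 0 lists. Without the 4 arrays of lowest weight ZT8 had 165 genes, ZT20 142 and the difference 1, with an amplitude ratio of -0.163.

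Leaving out 1 array in turn gave 2592 to 3068 genes on average, 270 to 1143 at ZT0, 258 to 611 at ZT4, 54 to 129 at ZT8, 291 to 855 at ZT12, 96 to 363 at ZT16 and 121 to 338 at ZT20. Rhythmic genes ranged from 2469 to 3370 on chow and 1326 to 1669 on high fat diet, and genes with a difference in rhythm from 4 to 11. The peak shift ranged from -1.13 to -0.930 h, the amplitude ratio from -0.145 to -0.0580 and lists by diet from 18 to 19. Lists among rhythmic genes ranged from 4 to 8 on chow and 9 to 16 on high fat diet. Where this leaves 2 arrays in a group, the pooled spread of all groups was used.

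Replicate numbers did not pair the samples: residuals of the same number correlated at a median of 0.0206 between diets, against 0.0175 for different numbers. With the number as a block 2952 genes were called on average and 4 in the difference. For named genes, other settings kept the side of the threshold in 2953 cases, gained a call in 36, lost it in 31 and reversed it in 0. Leaving out 1 array kept it in 9740, gained a call in 34, lost it in 198 and reversed it in 0.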

Other observations

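The tests of this part were chosen only after the result was seen.

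Heat shock genes were lower on high fat diet at ZT16 relative to the other times, with a median log2 contrast of -0.19 (camera adjusted p = 6.63e-10; adjusted p = 0.0310 with an estimated correlation). It was the only list whose contrast between a time and the rest passed both ways. These p-values were adjusted over the lists within each time and not over the times. The pass with an estimated correlation is therefore not corrected for the choice of ZT16 among the times. With 1 of the 6 arrays of ZT16 left out at a time the median stayed between -0.24 and -0.18. The adjusted p with an estimated correlation then ran from 0.00731 without chow replicate 2 to 0.229 without chow replicate 1, an array of low weight (0.409), and it passed without 2 of the 6 arrays. Hspb1, a small heat shock protein chosen after its values were seen, stood at -0.997 at ZT16 and -0.69 at ZT0. Other lists were lower at ZT16 by preset camera too. These were the unfolded protein response (-0.26; 1.09e-10, and adjusted p = 0.218 with an estimated correlation), cell cycle (-0.16; 1.90e-05, and 0.350), interferon-stimulated genes (-0.16; 0.00115, and 0.562), T, NK and B cell genes (-0.22; 0.00458, and 0.247), macrophage markers (-0.18; 0.00698, and 0.708) and cholesterol synthesis (-0.12; 0.00698, and 0.747). Fatty acid synthesis genes had contrasts of -0.25 at ZT0 (1.45e-08; adjusted p = 0.506 with an estimated correlation) and 0.22 at ZT12 (2.54e-08; adjusted p = 0.380 with an estimated correlation). PPARA targets stood at 0.23 at ZT4 (2.60e-08; adjusted p = 0.722 with an estimated correlation), and macrophage markers at 0.43 at ZT0 (0.000279; adjusted p = 0.506 with an estimated correlation). Markers of sinusoidal endothelium (0.22; 0.0431, and adjusted p = 0.726 with an estimated correlation) and muscle (0.15; 0.0221, and 0.506) moved the same way at ZT0. At ZT4 stellate genes were higher (0.11; 0.0269, and 0.722) and pancreas and gut genes lower (-0.14; 0.0150, and 0.722). Macrophage markers (0.26; 7.90e-05, and 0.466) and T, NK and B cell genes (0.19; 0.00925, and 0.380) were higher at ZT12.

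When lists were tested by 100000 exchanges of diet labels within times, 24 of 40 passed for the average diet effect. The value tested was the mean difference of a list minus that of all tested genes. CAR and PXR genes, glutathione genes, ribosomal proteins, interferon-stimulated genes and PPARG and lipid droplet genes had an adjusted p of 5e-05 each (unadjusted 1e-05, the smallest possible), PPARA targets of 0.000333, cholesterol synthesis of 0.0008 and macrophage markers of 0.00379. Fatty acid synthesis did not pass (0.0774). Lists that camera had not called passed too, among them NAD synthesis (5e-05), insulin signalling (0.000615), adipose tissue (0.00358), hepatocyte identity (0.0139) and bile acid genes (0.0294). Relative to all tested genes their means were -0.09, -0.08, 0.16, -0.07 and -0.05 in that order. A few members can carry such a mean: bile acid genes had 6 of 24 higher and 6 lower, with a median of 0.02.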
